A study of Arabidopsis thaliana with 20 samples.

How the data were processed

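The series measured gene expression in seedlings of Arabidopsis thaliana, the thale cress, by RNA sequencing. Seedlings of the accession Col-3 served as wild type, and seedlings of a nup62 mutant carried a defect in NUP62, which encodes a protein of the central channel of the nuclear pore. Each genotype was sprayed either with spores of the grey mould fungus Botrytis cinerea (strain B05.10 per the file headers) or with the spore-free PDB medium, called mock here, and was exposed for 24 h. Per the labels' protocols, seeds were chilled for 3 days and seedlings grew on MS plates at 22 °C with 16 h of light and 8 h of darkness. Messenger RNA was enriched on oligo(dT) beads and copied with random hexamers. The 20 libraries formed 4 groups of 5, which the labels call biological replicates, and each library was placed by its genotype and treatment labels.

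The deposited table gave a raw count per gene and library and, beside it, an FPKM value. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2 2.1.0, HTSeq 0.6.0 and DESeq2 1.36.0 with the genome build TAIR10. The notes give no role or order for these tools, and the annotation release and the strand setting of the counting are not given in the sources used here. Counts of a gene and of a partner that overlaps it on the opposite strand can therefore not be told apart. Each FPKM value deposited by the authors equalled the count divided by the column total and by a gene length, which varied between libraries by at most 2.8e-14 of its value in any gene. That length lay within 1e-06 of the length column of the table, relative to it, for 58.1% of the 25019 genes with a count. The symbol of AT1G24260 (SEP3 in the reference) had been turned into a date in the deposited table.

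The table held 34218 genes, of which 9199 had no count in any library. All columns of counts and FPKM were matched to a sample by name. Total counts ran from 37.208 to 57.551 M per library. Between replicates of a group, chi-square values per gene lay between 4.41 and 15.6, so that no pair of libraries agreed within sampling noise and all 20 were kept as separate replicates. Floors and bounds for genes at 0 cover counting error only.

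Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr with a minimum count of 10, a model with 1 mean per group over all 20 libraries, robust quasi-likelihood fits and 2-sided tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 19735 tested genes, which held 99.984% of all counts. The common dispersion was 0.00729. The 5 comparisons were infection in Col-3, infection in nup62, nup62 against Col-3 in mock libraries, the same in infected libraries, and their difference, called the interaction. Log2 fold changes are given with their standard error (SE), computed from the F statistic, and are nup62 minus Col-3 or infected minus mock. Standard deviations (SD) are over the 5 libraries of a group. Adjusted p values of single genes come from edgeR unless DESeq2 or limma-trend is named beside them.

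The groups, the comparisons, the 22 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each call was repeated with a correlation estimated from the data. The lists covered nucleoporins, camalexin, jasmonate, ethylene and ERF factors, antifungal proteins, salicylate, pattern-triggered immunity, photosynthesis, aliphatic and indole glucosinolates, lignin precursors, flavonoids and anthocyanins, abscisic acid, senescence, heat shock, elongation growth, circadian clock, flowering time, oxidative stress and detoxification, and cell division. Root tissue markers and seed storage markers stood for other material a seedling sample can hold. Of 356 list entries, 1 was left out because its symbol belonged to another gene in the reference, and 9 were matched by locus only.

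Named in each comparison were NUP62; the 5 genes with the largest rise and the 5 with the largest fall among genes past the threshold, with a mean log2 CPM of at least 3 and no overlap between the libraries of both groups; from each list called by camera, the member with the smallest p and the past-threshold member with the largest change; and 13 genes fixed by name. No overlap rule was used for the interaction. SAG12, fixed by name, did not pass the filter. Symbols follow the deposited table or the fixed lists.

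An infection index was computed per library as the mean log2 CPM (prior count 2) of genes that rose minus that of genes that fell at least 2-fold in the infection effect averaged over both genotypes. Groups were compared by an exact permutation test. A gene with no count in a whole group was given as a bound, from a floor of 3 counts per library.

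Alternatives fixed in advance were RLE and upper-quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-trend on log2(FPKM + 1), only the 10 libraries compared, a replicate block, other definitions of the index and of the correlation, and each library left out in turn. Alternatives chosen after seeing the data left out Col3_mock replicate 1 and nup62_mock replicate 5, or removed from each library a smooth trend over exon length and GC content. Exon length and GC came from the reference TAIR10.1, in which 32548 loci of the table were found, 32518 of them with the same start and end. They covered 99.4% of tested genes. Matched random lists were 10000 draws of genes close to the members of a list in level, exon length and GC. For each library, the spread of long against short genes is the median deviation from the mean over libraries in the 20% of genes with the longest exons minus that in the 20% with the shortest, over genes with a mean log2 CPM of at least 3. Figures were drawn with matplotlib.

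The test was checked on simulated counts. For infection in Col-3, 200 of 19215 simulated genes were changed; edgeR recovered 88.1% of those changed 1.5-fold, 94.0% at 2-fold and 100% at 4-fold, with 6 other genes called. For the interaction the shares were 74.6%, 86.6% and 98.5%, with 10 others. The raised list was called and 0 of the unchanged lists were. Simulated genes were drawn independently, without a length or GC trend, and few of them changed. The check therefore does not cover the preset correlation of camera, nor scaling where many genes change. Fungal reads were not analysed here, so the amount of fungus per seedling is not known.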

Results

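Gene expression was measured in 20 RNA-seq libraries of Arabidopsis seedlings, 5 each of Col-3 mock, nup62 mock, Col-3 infected and nup62 infected with Botrytis cinerea. Totals were 46.3 ± 7.44 M counts (SD, n = 5) in Col-3 mock, 43.8 ± 2.92 M in nup62 mock, 46.8 ± 6.39 M in Col-3 infected and 42.1 ± 2.52 M in nup62 infected libraries. The 10 most counted genes took 9.71% of the counts in Col-3 mock and 7.44% in Col-3 infected libraries, against 8.69% and 8.09% in nup62. The first and second principal components of log2 CPM held 40.9% and 18.6% of the variance.

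NUP62 (AT2G45000, chromosome 2, 18564017 to 18567892 on the + strand, TAIR10), the gene named by the mutant, was counted in every library. It stood at 13.6 ± 0.853 CPM (SD, n = 5) in Col-3 mock and 9.41 ± 1.09 CPM in nup62 mock libraries, a log2 difference of -0.53 ± 0.08 (SE, edgeR adjusted p = 7.77e-07). After infection it stood at 13.0 ± 0.687 CPM in Col-3 and 17.3 ± 1.55 CPM in nup62, a log2 difference of 0.41 ± 0.08 (adjusted p = 3.41e-05). The transcript thus rose on infection in nup62 (0.88 ± 0.08, adjusted p = 2.3e-11), while its value in Col-3 was -0.06 ± 0.08 (adjusted p = 0.496). The place of the mutation in the gene is not given in the sources used here, so counts over the whole gene do not tell how much intact transcript was made.

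**Figure D1:**
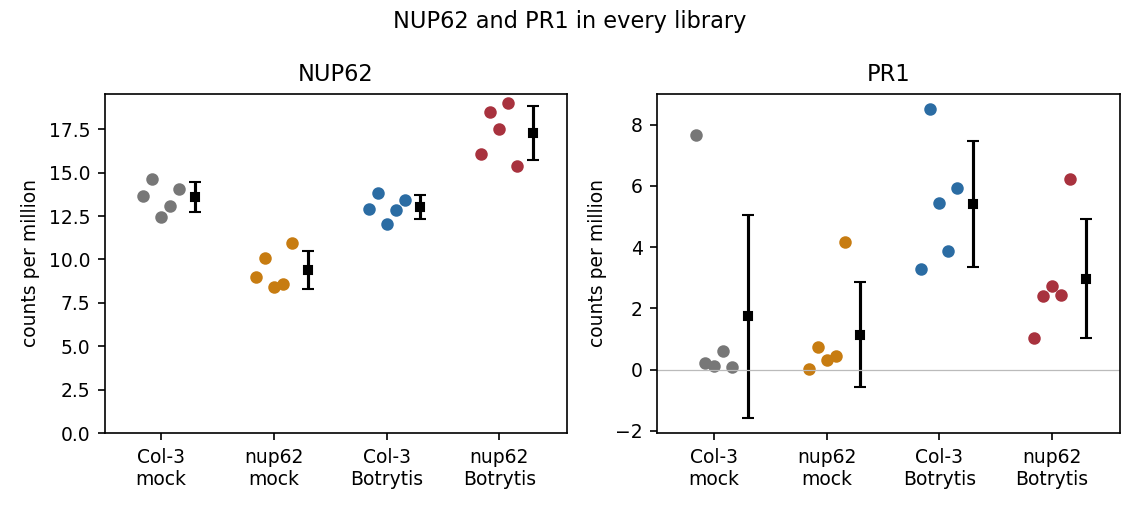
Counts per M of NUP62 and of PR1, a marker of salicylate signalling, in each library (points) with the group mean and SD (squares and bars, n = 5). NUP62 lay between 8.391 and 10.96 CPM in nup62 mock libraries and between 15.37 and 19.02 CPM in nup62 infected ones. PR1 reached 7.65 CPM in Col-3 mock replicate 1 and 4.16 CPM in nup62 mock replicate 5.

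Col-3 mock libraries stood apart in the balance of long and short transcripts. Long minus short genes was -0.207 ± 0.097 (log2, SD, n = 5) in Col-3 mock, 0.084 ± 0.042 in nup62 mock, 0.080 ± 0.042 in Col-3 infected and 0.039 ± 0.077 in nup62 infected libraries. GC-rich minus GC-poor genes was 0.123 ± 0.039, 0.001 ± 0.025, -0.103 ± 0.016 and -0.008 ± 0.020 in the same order. On this measure both Col-3 groups stood apart from the nup62 libraries, in opposite directions and with no overlap. In infection in Col-3, the median log2 change was 0.18 over the longest 20% of genes and -0.12 over the shortest 20%; in nup62 against Col-3 mock it was 0.16 and -0.13, and in the interaction -0.18 and 0.15. In infection in nup62 (-0.03 and 0.03) and in nup62 against Col-3 under infection (-0.02 and 0.02) it was near 0. Over genes rich and poor in GC, the median was -0.166 and 0.067 in infection in Col-3, 0.002 and 0.008 in infection in nup62, -0.113 and 0 in nup62 against Col-3 mock, 0.059 and -0.053 in the same under infection, and 0.188 and -0.055 in the interaction.

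**Figure D2:**
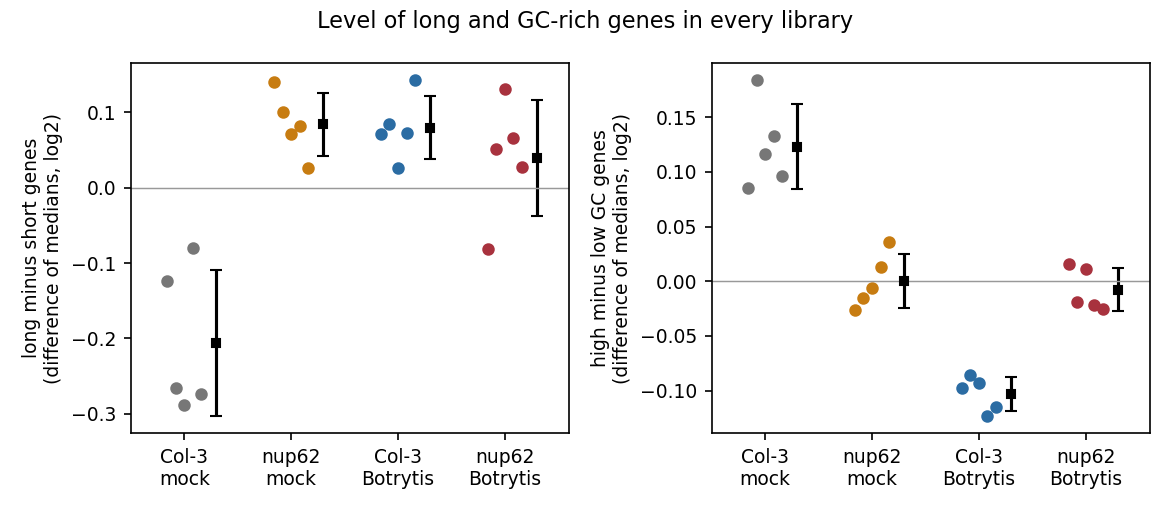
Left, the median log2 deviation of the longest 20% of genes minus that of the shortest 20%, and right, the same for genes rich and poor in GC, in each library (points), with group means and SD (squares and bars, n = 5). All 5 Col-3 mock libraries lay below 0 on the left, at -0.289 to -0.0804, as did 1 nup62 infected library at -0.0809. On the right, the Col-3 infected libraries lay at -0.1236 to -0.0854, below every nup62 library, and the Col-3 mock libraries lay above every nup62 library.

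The response of the wild type to the fungus was a broad rise of defence genes. Genes of salicylate signalling, pattern recognition, camalexin synthesis and indole glucosinolates rose together, and nuclear photosynthesis genes fell. With an estimated correlation the salicylate and pattern-triggered immunity lists held, and camalexin (adjusted p = 0.134), indole glucosinolates (0.0714) and photosynthesis (0.147) did not. Among well-counted genes the largest rises were of PCR1 (AT1G14880), a cadmium resistance protein, from 3.54 ± 3.23 to 102 ± 20.3 CPM (SD, n = 5; 29.8-fold), LURP1 (24.9-fold), UGT76B1 (21.3-fold), a glycosyltransferase of immune signals, LHT7 (19.9-fold) and PCC1 (18.6-fold). Without Col-3 mock replicate 1, the log2 change of PCR1 moved from 4.90 to 5.56 and that of UGT76B1 from 4.41 to 5.04, so the order of these genes depended on that library. The largest falls were of the ammonium transporter AMT1-2 (log2 fold change -1.51 ± 0.10, SE), GSTU17 (-1.36 ± 0.11), AT1G62510 (-1.31 ± 0.09), RD22 (-1.28 ± 0.10) and the aldolase FBA5 (-1.26 ± 0.07). By the rule for naming them, all 10 had no overlap between the 5 mock and 5 infected libraries; adjusted p ran from 4.7e-18 (LHT7) to 2.27e-07 (UGT76B1).

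Of 23 tested salicylate genes, 21 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 5.86e-25, adjusted p = 0.00731 with an estimated correlation). EDS1, a central regulator of immunity, rose by 1.75 ± 0.06 (log2, SE, adjusted p = 3.51e-22), ICS1, which makes the salicylate precursor isochorismate, by 1.19 ± 0.05 (2.33e-19), and the transcription factor WRKY62 by 5.27 ± 0.36 from a mock level of 0.103 CPM. Of 22 genes of pattern-triggered immunity 19 rose and 0 fell (20 and 0 adjusted over the list alone; adjusted p = 5.43e-16, and 0.00731 with an estimated correlation). They included LYK5, a receptor of fungal chitin (2.103 ± 0.08), the danger peptide precursor PROPEP2 (3.08 ± 0.48), FRK1 (1.64 ± 0.23) and the receptor-associated kinase BIK1 (0.52 ± 0.07). PR1, the classic salicylate marker, changed by 1.71 ± 0.97 (adjusted p = 0.144) because Col-3 mock replicate 1 alone held 7.65 CPM; without that library the change was 4.38 (adjusted p = 0.000974).

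Of 16 camalexin genes, which serve the main antifungal indole compound of Arabidopsis, 15 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 1.66e-12, adjusted p = 0.134 with an estimated correlation). PAD3, the last step of the pathway, rose by 3.19 ± 0.31 (SE), CYP71A13 by 3.80 ± 0.37, its regulator WRKY33 by 2.43 ± 0.11 and the exporter PEN3 by 1.57 ± 0.07. CYP71A13 has a near-identical neighbour, CYP71A12, so its counts are uncertain. Of 10 indole glucosinolate genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 2.8e-08, and adjusted p = 0.0714 with an estimated correlation). Among them were PEN2 (1.14 ± 0.06) and the regulator MYB122 (4.02 ± 0.61; 4.87 without Col-3 mock replicate 1). Of 11 antifungal protein genes 8 rose and 0 fell (9 and 0 over the list alone; adjusted p = 4.72e-05, and adjusted p = 0.124 with an estimated correlation). The defensins PDF1.2A (4.61 ± 0.38), PDF1.2B (4.195 ± 0.27) and PDF1.2C (4.87 ± 0.57) are near-identical copies whose split of reads is uncertain. Of 14 ethylene and ERF genes 10 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 5.37e-05, and adjusted p = 0.124 with an estimated correlation). ERF1B stood at 2.82 ± 0.41, ERF104 at 1.51 ± 0.09 and ORA59 at 1.17 ± 0.09. Of 14 oxidative stress genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 0.00305, and adjusted p = 0.479 with an estimated correlation). GSTU4 (3.29 ± 0.46) rose most among them, and NDA2 (1.70 ± 0.08) had the smallest edgeR p.

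Of 35 photosynthesis genes 34 fell and 0 rose (34 and 0 adjusted over the list alone), with a median log2 change of -0.48 (camera adjusted p = 4.14e-20, adjusted p = 0.147 with an estimated correlation). The Rubisco activase gene RCA fell most, by 0.80 ± 0.06 (SE, adjusted p = 4.61e-14), and LHCB1.1, which has near-identical copies, fell by 0.62 ± 0.05. With the length and GC trend of each library removed, the median was -0.32, 33 genes fell and LHCB1.1 fell by 0.33. The median was -0.291 with total-count scaling, and random lists matched on level, exon length and GC had -0.373 (middle 95% from -0.463 to -0.3). The jasmonate genes JAZ10 (0.87 ± 0.38, adjusted p = 0.0636) and VSP2 (0.91 ± 0.45, adjusted p = 0.0913) did not pass the threshold. JAZ10 passed with limma-trend on log2(FPKM + 1) (0.0163), with only the 10 libraries compared (0.0331) and without Col3_mock replicate 1 and nup62_mock replicate 5 (0.0179). JAZ10 also passed without nup62 mock replicate 3 (0.0471) or 5 (0.00893) or Col-3 infected replicate 1 (0.0464), and VSP2 without the last (0.0151). The other 12 lists were not called, with adjusted p from 0.102 (aliphatic glucosinolates, heat shock and senescence) to 0.763 (flowering time). Heat shock (0.044) and nucleoporins (0.0211) were called with the trend removed, and jasmonate (0.0372) with only the 10 libraries compared. Senescence was called without Col3_mock replicate 1 and nup62_mock replicate 5 (0.0174) or the first alone (0.0353), and aliphatic glucosinolates without Col-3 mock replicate 3 (0.048).

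In all, 11464 of 19735 genes changed in Col-3, 6355 up and 5109 down; 1603 changed at least 2-fold, 1510 of them up. Of the calls 55.4% were up, 49.9% with RLE scaling, 47.0% with upper-quartile scaling, 47.5% with the length and GC trend removed and 80.4% with limma-trend on log2(FPKM + 1), so which direction held the majority depended on the processing.

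The nup62 mutant responded with rises of the same gene lists and fewer called genes. With an estimated correlation the rise of the oxidative stress list did not hold (adjusted p = 0.331). CYP71A13 (18.0-fold), the receptor-like kinase CRK7 (AT4G23150, 13.7-fold), AT3G22600 (12.6-fold), UGT76B1 (12.6-fold) and PAD3 (12.3-fold) rose most among well-counted genes. Without nup62 mock replicate 5, the log2 change of UGT76B1 moved from 3.65 to 4.25. The largest falls were of the pectin lyase-like gene AT1G60590 (log2 fold change -1.10 ± 0.10, SE), AT2G20670 (-1.09 ± 0.09), LEA2 (-1.07 ± 0.13), the inactive amylase BAM9 (-1.01 ± 0.08) and AMT1-2 (-1.001 ± 0.10). Adjusted p lay between 2.08e-12 (BAM9) and 1.1e-05 (UGT76B1), with no overlap between mock and infected libraries.

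Of 23 salicylate genes 19 rose and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 3.14e-28, and 0.00318 with an estimated correlation). ALD1 rose by 3.25 ± 0.40 (SE) and ICS1 by 0.90 ± 0.05. Of 22 pattern-triggered immunity genes 17 rose and 0 fell (17 and 0 adjusted over the list alone; adjusted p = 4.34e-19, and 0.00313 with an estimated correlation). The chitin receptor kinase CERK1 stood at 0.94 ± 0.05, the receptor RLP23 at 2.71 ± 0.21, FRK1 at 0.85 ± 0.22 and BIK1 at 0.71 ± 0.07. Of 16 camalexin genes 15 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 1.48e-24, and 0.0165 with an estimated correlation). PAD3 stood at 3.62 ± 0.32, CYP71A13 at 4.17 ± 0.43, PEN3 at 1.51 ± 0.07 and WRKY33 at 1.42 ± 0.11. Of 10 indole glucosinolate genes 9 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 4.16e-13, and 0.0076 with an estimated correlation). IGMT1 stood at 1.72 ± 0.09 and MYB122 at 2.86 ± 0.70, or 3.68 without nup62 mock replicate 4. Of 14 ethylene and ERF genes 11 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 1.11e-06, and 0.0325 with an estimated correlation). ORA59 stood at 1.67 ± 0.10.

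Of 11 antifungal genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 1.1e-13, and 0.00318 with an estimated correlation). PDF1.2A, PDF1.2B and PDF1.2C had no count in any of the 5 nup62 mock libraries, where 3 counts per library would be 0.068 CPM. Against that floor they rose at least 18.5-fold, 25.1-fold and 9.59-fold. Of 15 abscisic acid genes 0 rose and 10 fell (0 and 10 adjusted over the list alone; adjusted p = 5.76e-06, and 0.0076 with an estimated correlation), including NCED3, a key enzyme of abscisic acid synthesis (-1.46 ± 0.13), and LTP3 (-2.09 ± 0.38). Of 14 oxidative stress genes 7 rose (7 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.331 with an estimated correlation). GSTU4 stood at 2.05 ± 0.46, and at 3.005 without nup62 mock replicate 5; NDA2 stood at 1.22 ± 0.08. Of 11 senescence genes 5 rose (6 adjusted over the list alone; adjusted p = 0.0126, and adjusted p = 0.331 with an estimated correlation). SAG13 stood at 2.73 ± 0.30 and SAG21 at 1.31 ± 0.09.

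Of 35 photosynthesis genes 5 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.0127, adjusted p = 0.69 with an estimated correlation). RBCS1B (-0.25 ± 0.07, SE) and RBCS2B (-0.24 ± 0.05), 2 near-identical Rubisco genes, were among them, and LHCB1.1 stood at -0.13 ± 0.05 and did not pass (adjusted p = 0.0581). LHCB1.1 passed with RLE scaling (adjusted p = 0.0337), upper-quartile scaling (0.0126), the stricter filter (0.0496), DESeq2 (0.00971), limma-trend on log2(FPKM + 1) (0.007) and the length and GC trend removed (0.000324). It also passed without Col-3 mock replicate 1, nup62 mock replicate 3, nup62 infected replicate 1 or any 1 of the 5 Col-3 infected libraries (0.0124 to 0.0468). With the length and GC trend removed, 21 fell and the median was -0.13; random matched lists had -0.047 (middle 95% from -0.125 to 0.017), a range that holds the list. The list was not called without nup62 infected replicate 3 (adjusted p = 0.0537). Of 13 cell division genes 3 fell (2 adjusted over the list alone; adjusted p = 0.0387, and adjusted p = 0.446 with an estimated correlation). CDC20.1 stood at -0.46 ± 0.12, and at -0.509 with the trend removed (adjusted p = 0.00126). The call of the cell division list was lost with the trend removed (adjusted p = 0.0672), upper-quartile scaling (0.0593) and only the 10 libraries compared (0.061). That list was also not called without nup62 mock replicate 1 (0.0615) or 3 (adjusted p = 0.0922) or nup62 infected replicate 5 (0.0674). JAZ10 (-0.15 ± 0.37, adjusted p = 0.811), VSP2 (-0.57 ± 0.45, adjusted p = 0.387) and PR1 (1.39 ± 1.02, adjusted p = 0.357) did not pass. Without Col3_mock replicate 1 and nup62_mock replicate 5, PR1 rose by 2.93 (adjusted p = 0.00297). The other 9 lists were not called, with adjusted p from 0.0586 (elongation growth) to 0.869 (jasmonate). Elongation growth was called with no filter (0.0292), the stricter filter (0.049), without Col3_mock replicate 1 and nup62_mock replicate 5 (0.0414), the latter alone (0.0341) or nup62 infected replicate 2 (0.0424). Flavonoids were called with the stricter filter (0.0272) and without nup62 mock replicate 1 (0.0267) or nup62 infected replicate 1 (0.039).

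In nup62, 5562 genes changed, 3221 up and 2341 down; 794 changed at least 2-fold, 714 of them up. Of the calls 57.9% were up, 45.6% with upper-quartile scaling, 41.5% with the length and GC trend removed and 62.5% with limma-trend on log2(FPKM + 1).

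Without the fungus, genes of the nuclear pore were higher in the mutant than in Col-3, the only list called in mock libraries whose call held with an estimated correlation. Photosynthesis genes were lower with a smaller camera p, and that call did not hold (adjusted p = 0.476). NUP98B, a nucleoporin, stood at 10.5 ± 1.1 CPM in Col-3 mock and 57.7 ± 2.33 CPM in nup62 mock libraries (SD, n = 5; 5.51-fold). The other largest rises were of AT1G63530 (15.5-fold), the ubiquitin ligase gene AT5G60250 (7.5-fold), the storage protein gene VSP1 (4.41-fold) and the defensin-like gene AT3G59930 (4.11-fold). RLP23, which recognises a peptide of microbial toxins, was lower (log2 difference -2.09 ± 0.22, SE), as were AT1G15125 (-2.02 ± 0.11), the glucose-6-phosphate dehydrogenase gene G6PD3 (-1.88 ± 0.11), the gene of a probably inactive acid phosphatase, PAP1 (AT1G13750, -1.71 ± 0.12) and the sugar transporter gene SWEET12 (-1.67 ± 0.08). Adjusted p lay between 4.05e-30 (AT1G63530) and 0.00223 (VSP1, a near copy of VSP2).

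Of 29 nucleoporin genes, 17 were higher and 3 lower in nup62 (17 and 3 adjusted over the list alone), with a median log2 difference of 0.24 (camera adjusted p = 8.58e-07, and 0.0292 with an estimated correlation). With the length and GC trend removed, 14 were higher and 6 lower, with a median of 0.12. The list includes NUP62 itself, whose difference of -0.53 before that removal was the lowest of all members. Of 35 photosynthesis genes 33 were lower and 0 higher (33 and 0 adjusted over the list alone), with a median of -0.35 (adjusted p = 8.2e-15, and adjusted p = 0.476 with an estimated correlation). The median was -0.21 with total-count scaling and -0.155 with the trend removed; random lists matched on level, exon length and GC had -0.187 (middle 95% from -0.27 to -0.102). LHCB4.1 differed by -0.48 ± 0.05 (SE) and PSAO by -0.46 ± 0.05. With the trend removed, 22 were lower and 1 higher, LHCB4.1 differed by -0.20, and LHCB1.1 moved from -0.08 ± 0.05 (adjusted p = 0.178) to 0.16 (adjusted p = 0.000528). Without Col3_mock replicate 1 and nup62_mock replicate 5, LHCB1.1 stood at -0.136 (adjusted p = 0.0347).

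Of 16 camalexin genes 10 were lower and 0 higher (10 and 0 adjusted over the list alone; camera adjusted p = 0.0303, and adjusted p = 0.745 with an estimated correlation). NAC042, a regulator of the pathway, differed by -1.93 ± 0.37 (SE), PEN3 by -0.51 ± 0.07, PAD3 by -1.03 ± 0.33 (adjusted p = 0.0148) and CYP71A13 by -1.33 ± 0.52 (adjusted p = 0.0408). With only the 10 libraries compared, PAD3 (adjusted p = 0.0776) and CYP71A13 (0.0647) were not called. CYP71A13 also lost its call with a replicate block (0.0658), with limma-trend on log2(FPKM + 1) (0.0863), with the length and GC trend removed (0.0868) and in 6 of the 20 fits without 1 library. Without Col-3 mock replicate 1 alone, PAD3 stood at -0.69 (adjusted p = 0.0542), CYP71A13 at -0.83 (adjusted p = 0.156), and the list was not called (adjusted p = 0.0647), while NAC042 and PEN3 kept their calls. Without both Col3_mock replicate 1 and nup62_mock replicate 5, PAD3 (-0.915, adjusted p = 0.012), CYP71A13 (-1.31, adjusted p = 0.028) and the list (adjusted p = 0.00615) were called. Of 11 antifungal genes 8 were lower and 0 higher (8 and 0 adjusted over the list alone; adjusted p = 0.009, adjusted p = 0.476 with an estimated correlation and 0.128 with only the 10 libraries compared). PDF1.2A, PDF1.2B and PDF1.2C, at 0 in all nup62 mock libraries, were at least 4.17-fold, 4.23-fold and 1.45-fold lower. ORA59, a regulator of these defensins, differed by -1.06 ± 0.10.

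Of 9 flavonoid genes 6 were higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.0407, and adjusted p = 0.607 with an estimated correlation). FLS1 stood at 0.68 ± 0.08 (SE) and DFR at 2.40 ± 0.68. Of 15 lignin precursor genes 8 were higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 0.0401, and adjusted p = 0.745 with an estimated correlation). PAL2 stood at 0.47 ± 0.06. Without Col3_mock replicate 1 and nup62_mock replicate 5 neither list was called (adjusted p = 0.0847 and 0.172). The flavonoid list was also not called with the stricter filter (0.0812). Both lists lost their calls without some single libraries, such as nup62_mock replicate 5 (0.0651 and 0.104). Of 6 flowering time genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.0401, and adjusted p = 0.476 with an estimated correlation). Among them were SOC1, a promoter of flowering (1.21 ± 0.07). The largest difference was in AP1, at 0.277 ± 0.193 CPM in nup62 and 0.0104 ± 0.0144 CPM in Col-3 mock libraries, the latter under the floor of 0.068 CPM. The list was not called without nup62 mock replicate 4 (adjusted p = 0.0506).

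Of the other genes fixed by name, BIK1 was lower (-0.25 ± 0.07, SE, adjusted p = 0.00519; 0.248 with limma-trend on log2(FPKM + 1)), and JAZ10 (0.95 ± 0.39, adjusted p = 0.0484) and FRK1 (0.57 ± 0.23, adjusted p = 0.0463) passed narrowly. JAZ10 lost its call in 14 and FRK1 in 12 of the 20 fits that each left out 1 library, JAZ10 at 0.47 (adjusted p = 0.19) without nup62 mock replicate 5 and FRK1 at 0.40 (adjusted p = 0.148) without nup62 mock replicate 4. Both calls were also lost with RLE scaling (0.0527 and 0.0528), no filter (0.064 and 0.0575) and a replicate block (0.0817 and 0.0801). The same held with only the 10 libraries compared (0.118 and 0.122) and with the trend removed (0.085 and 0.0751). WRKY33 (0.25 ± 0.11, adjusted p = 0.081), VSP2 (0.70 ± 0.45, adjusted p = 0.21), ICS1 (-0.07 ± 0.06, adjusted p = 0.312) and PR1 (-0.55 ± 1.07, adjusted p = 0.696) did not pass. WRKY33 passed with limma-trend on log2(FPKM + 1) (0.00546) and without Col3_mock replicate 1 and nup62_mock replicate 5 (0.0101), the first alone (0.00405) or nup62 mock replicate 3 (0.0391). ICS1 passed without Col-3 mock replicate 3 (-0.127, adjusted p = 0.0339). Root tissue markers had 4 tested members of 13, too few for a list test: NRT2.1 (-0.73 ± 0.24), PYK10 (-0.50 ± 0.09) and SHR (-0.23 ± 0.06) were lower in nup62, while SCR stood at -0.09 ± 0.05 (adjusted p = 0.171). The other root markers did not pass the filter, so how much root tissue the samples held is uncertain. Of 9 seed storage markers 0 passed the filter. The other 13 lists were not called, with adjusted p from 0.0798 (oxidative stress and detoxification) to 0.839 (jasmonate). Oxidative stress was called without Col3_mock replicate 1 and nup62_mock replicate 5 (0.00615) or the latter alone (0.00308), and pattern-triggered immunity with the trend removed (0.0193).

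Between mock libraries, 10258 genes differed, 5109 higher and 5149 lower in nup62; 819 differed at least 2-fold, 567 of them higher. Of the calls 49.8% were higher, 46.8% with RLE scaling, 51.6% with upper-quartile scaling, 53.0% with the length and GC trend removed and 72.6% with limma-trend on log2(FPKM + 1).

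Under infection, defence genes were lower in nup62 than in Col-3 across most of the lists that rose on infection, and nucleoporin genes were again higher. With an estimated correlation, the nucleoporin and pattern-triggered immunity lists held; salicylate (adjusted p = 0.0843), camalexin (0.344), and indole glucosinolates, oxidative stress, antifungal proteins and ethylene and ERF (each 0.276) did not. AT1G63530 (16.9-fold), AT5G60250 (7.89-fold), AT3G59930 (5.56-fold), the protochlorophyllide reductase gene PORA (5.51-fold) and NUP98B (5.34-fold) were highest in nup62 relative to Col-3. Lowest were the receptor-like kinase gene AT1G56120 (log2 difference -2.34 ± 0.13, SE), the receptor-like protein gene RLP38 (AT3G23120, -2.22 ± 0.16), PAP1 (AT1G13750, -2.096 ± 0.11), AT1G13470 (-2.05 ± 0.14) and the glycosyltransferase gene AT3G61280 (-1.94 ± 0.14). Adjusted p lay between 1.33e-30 (AT1G63530) and 9.31e-10 (RLP38), with no overlap between the genotypes.

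Of 22 pattern-triggered immunity genes 14 were lower and 0 higher in nup62 (15 and 0 adjusted over the list alone; camera adjusted p = 1.34e-09, and 0.036 with an estimated correlation). Among them were RLP23 (-1.71 ± 0.17, SE) and RLP42 (-1.17 ± 0.08), a receptor of fungal polygalacturonases. BIK1 (-0.06 ± 0.07, adjusted p = 0.534) and FRK1 (-0.21 ± 0.21, adjusted p = 0.471) did not pass. Of 23 salicylate genes 20 were lower and 0 higher (20 and 0 adjusted over the list alone), with a median of -0.87 (adjusted p = 1.87e-11, and adjusted p = 0.0843 with an estimated correlation). DLO1, a salicylate hydroxylase, differed by -2.04 ± 0.50, PAD4 by -0.98 ± 0.06 and ICS1 by -0.36 ± 0.05, while PR1 stood at -0.87 ± 0.91 (adjusted p = 0.493). Of 29 nucleoporin genes 20 were higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 0.19 (adjusted p = 1.87e-11, and 0.00229 with an estimated correlation). NUP62 itself was among the higher ones (0.413).

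Of 16 camalexin genes 13 were lower and 0 higher (14 and 0 adjusted over the list alone; camera adjusted p = 8.97e-05, and adjusted p = 0.344 with an estimated correlation). The transporter gene PDR12 differed by -1.10 ± 0.24 (SE), WRKY33 by -0.77 ± 0.10, PEN3 by -0.57 ± 0.07 and CYP71A13 by -0.96 ± 0.30 (adjusted p = 0.0168; 0.0687 with DESeq2). PAD3 stood at -0.60 ± 0.27 and did not pass (adjusted p = 0.0912), but passed with only the 10 libraries compared (0.011) and without Col3_mock replicate 1 and nup62_mock replicate 5 (0.0216) or the first alone (0.0374). Of 10 indole glucosinolate genes 8 were lower and 0 higher (8 and 0 adjusted over the list alone; adjusted p = 0.00141, and adjusted p = 0.276 with an estimated correlation). MYB122 stood at -1.55 ± 0.47 and PEN2 at -0.44 ± 0.06. Of 14 oxidative stress genes 10 were lower and 0 higher (10 and 0 adjusted over the list alone; adjusted p = 9.54e-05, and adjusted p = 0.276 with an estimated correlation). GSTU1 stood at -1.17 ± 0.33 and NDA2 at -0.93 ± 0.08. Of 11 antifungal genes 8 were lower and 0 higher (9 and 0 over the list alone; adjusted p = 0.00887, and adjusted p = 0.276 with an estimated correlation). PDF1.2A stood at -2.45 ± 0.31 and PDF1.2B at -1.60 ± 0.22. Of 14 ethylene and ERF genes 9 were lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 0.00792, and adjusted p = 0.276 with an estimated correlation). ERF1B stood at -1.21 ± 0.36, ERF15 at -0.98 ± 0.07 and ORA59 at -0.56 ± 0.09. Of 27 jasmonate genes 11 were lower and 2 higher (14 and 2 adjusted over the list alone; adjusted p = 0.0195, and adjusted p = 0.574 with an estimated correlation). AOC2 stood at -0.97 ± 0.11 and JAR1, which makes the active hormone, at -0.35 ± 0.04; JAZ10 (-0.07 ± 0.37, adjusted p = 0.902) and VSP2 (-0.79 ± 0.44, adjusted p = 0.176; 0.0376 without Col-3 infected replicate 1) did not pass.

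Some lists of metabolism and development were higher in nup62, and none of these calls held with an estimated correlation. Of 15 lignin precursor genes 10 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.000172, and adjusted p = 0.276 with an estimated correlation). HCT stood at 0.48 ± 0.05 (SE) and CCR2 at -0.79 ± 0.19. Of 13 aliphatic glucosinolate genes 8 were higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 0.00128, and adjusted p = 0.276 with an estimated correlation). The regulator MYB29 stood at 0.89 ± 0.06. Of 9 flavonoid genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone; adjusted p = 0.0328, and adjusted p = 0.327 with an estimated correlation). TT4 stood at 0.94 ± 0.09 and FLS1 at 0.82 ± 0.09. Upper-quartile scaling (adjusted p = 0.0523) and no filter (0.089) ended the flavonoid call. So did leaving out Col-3 infected replicate 1 (adjusted p = 0.0928) or nup62 infected replicate 1 (0.0717). Of 6 flowering time genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.0166, and adjusted p = 0.276 with an estimated correlation). SOC1 stood at 0.59 ± 0.07. Of 35 photosynthesis genes 9 were higher and 2 lower (9 and 2 adjusted over the list alone), with a median of 0.06 (adjusted p = 0.0157, and adjusted p = 0.667 with an estimated correlation); RBCS1B stood at 0.43 ± 0.07 and LHCB1.1 at 0.40 ± 0.05. That call ended with the length and GC trend removed (adjusted p = 0.312) and without nup62 infected replicate 1 (adjusted p = 0.0907). Random lists matched on level, exon length and GC had a higher median of 0.173, and 2.02% of them lay below the photosynthesis list. Photosynthesis genes were thus not raised relative to genes alike in these features. The other 6 lists were not called, with adjusted p from 0.108 (heat shock) to 0.965 (cell division). Senescence was called with only the 10 libraries compared (0.0205).

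Between infected libraries, 7900 genes differed, 3683 higher and 4217 lower in nup62; 652 differed at least 2-fold, 443 of them lower. Of the calls 46.6% were higher, 47.2% with RLE scaling, 54.1% with upper-quartile scaling, 50.5% with the length and GC trend removed and 35.9% with limma-trend on log2(FPKM + 1), so which direction held the majority depended on the processing.

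The interaction asks which genes responded differently in the mutant. Of 605 genes whose change differed at least 2-fold, 563 had a lower log2 change in nup62 than in Col-3. Such a difference can come from a higher nup62 mock level as well as from a lower infected level. Lowest among well-counted genes were NUDT21 (-2.29 ± 0.23, SE), a Nudix hydrolase gene, the mitochondrial carrier gene PUMP4 (-2.25 ± 0.26), the deadenylase gene CAF1-9 (-2.24 ± 0.27), AT1G56120 (-2.00 ± 0.21) and LHT7 (-1.96 ± 0.23). NUDT21 stood at 6.46 ± 1.86 CPM in Col-3 mock and 18.4 ± 4.1 CPM in Col-3 infected libraries, but at 15.5 ± 1.07 and 9.02 ± 0.861 CPM in nup62 (SD, n = 5). Highest were GAD4 (1.17 ± 0.11), SAUR62 (1.06 ± 0.12), AT1G15125 (1.01 ± 0.15), AT1G49470 (0.96 ± 0.11) and AT1G56000 (0.96 ± 0.24). Adjusted p lay between 1.95e-08 (GAD4) and 0.00356 (AT1G56000), and NUP62 itself differed by 0.94 ± 0.11 (adjusted p = 1.04e-07).

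Of 23 salicylate genes the change was lower in nup62 for 16 and higher for 0 (16 and 0 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 5.83e-07, and adjusted p = 0.383 with an estimated correlation). WRKY38 differed by -2.82 ± 0.46 (SE; -3.60 without Col-3 mock replicate 1), EDS1 by -0.82 ± 0.09 and ICS1 by -0.29 ± 0.08, and PR1 stood at -0.32 ± 1.41 (adjusted p = 0.883). Of 22 pattern-triggered immunity genes 9 were lower and 0 higher (9 and 0 adjusted over the list alone; adjusted p = 0.00311, and adjusted p = 0.39 with an estimated correlation). The median of -0.226 lay inside the middle 95% of random matched lists (-0.26 to 0.064). WRKY53 stood at -1.38 ± 0.16 and PROPEP2 at -1.74 ± 0.66 (adjusted p = 0.0364). PROPEP2 lost its call in 10 of the 20 fits without 1 library, with -1.48 (adjusted p = 0.094) without nup62 mock replicate 4. A replicate block ended that call too (-1.669, adjusted p = 0.062). FRK1 (-0.78 ± 0.31, adjusted p = 0.0587) and BIK1 (0.19 ± 0.10, adjusted p = 0.15; 0.0472 without nup62 infected replicate 5) did not pass. FRK1 passed with limma-trend on log2(FPKM + 1) (0.0236) and without Col3_mock replicate 1 and nup62_mock replicate 5 (0.0145). It also passed without Col-3 mock replicate 1 (0.0199), nup62 mock replicate 1 (0.0203) or 5 (0.0437) or nup62 infected replicate 2 (0.0335). Of 12 heat shock genes 7 were lower and 0 higher (8 and 0 adjusted over the list alone; adjusted p = 0.00345, and adjusted p = 0.383 with an estimated correlation). DREB2A stood at -1.23 ± 0.21 and ROF1 at -0.69 ± 0.08. Of 13 aliphatic glucosinolate genes 8 were higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.00324, and adjusted p = 0.553 with an estimated correlation). SOT18 stood at 0.73 ± 0.08 and, with the length and GC trend removed, at 0.46.

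Of 35 photosynthesis genes the change was higher in nup62 for 33 and lower for 0 (34 and 0 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 3.88e-24, and adjusted p = 0.383 with an estimated correlation). LHCB4.2 fell from 4603 ± 253 to 2811 ± 161 CPM in Col-3 and stood at 3343 ± 176 and 3374 ± 251 CPM in nup62 (SD, n = 5), an interaction of 0.72 ± 0.08 (SE). With the length and GC trend removed, 20 were higher and 1 lower, the median was 0.18, LHCB4.2 stood at 0.37 and LHCB1.1 moved from 0.49 to 0.16. The response of WRKY33 was lower in nup62 (-1.01 ± 0.16, adjusted p = 5.95e-05) and that of ORA59 higher (0.49 ± 0.14, adjusted p = 0.00473; 0.118 with limma-trend on log2(FPKM + 1)). PAD3 (0.43 ± 0.43, adjusted p = 0.466), CYP71A13 (0.37 ± 0.60, adjusted p = 0.669), JAZ10 (-1.02 ± 0.53, adjusted p = 0.146) and VSP2 (-1.48 ± 0.63, adjusted p = 0.074; 0.0483 with DESeq2, 0.0365 without nup62 mock replicate 3 and 0.0153 without Col-3 infected replicate 1) did not pass. No fold is given for PDF1.2A, which had no count in nup62 mock libraries. The other 15 lists were not called, with adjusted p from 0.144 (jasmonate) to 0.884 (elongation growth). Indole glucosinolates (0.0474) and nucleoporins (0.0379) were called with the trend removed, and jasmonate without nup62 mock replicate 3 (0.0037). Of 16 camalexin genes 4 were lower and 12 did not pass.

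**Figure D3:**
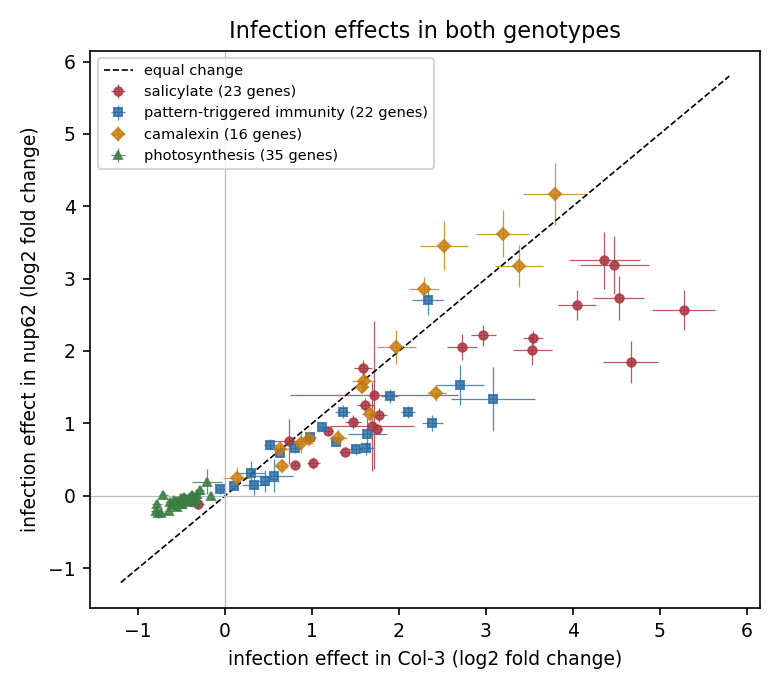
Log2 fold change on infection in Col-3 (horizontal) and nup62 (vertical) for the tested genes of 4 lists, with SE bars and a dashed line of equal change. Salicylate genes lie mostly below the line at a median of 1.75 in Col-3 and 1.39 in nup62, camalexin genes near it at 1.63 and 1.46.

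Over all genes, 7501 showed an interaction, 3618 higher and 3883 lower in nup62; 48.2% were higher, 52.3% with RLE scaling, 52.9% with upper-quartile scaling, 48.2% with the length and GC trend removed and 15.8% with limma-trend on log2(FPKM + 1). The infection effects of both genotypes, which share no library, had a Pearson correlation of 0.673 and a Spearman correlation of 0.428 across genes, which are not independent replicates. Of 673 genes changed at least 2-fold in both, 667 changed in the same direction, against 64.5 shared genes for independent lists. Over 1072 genes changed at least 2-fold in the mean infection effect, the median ratio of the nup62 to the Col-3 log2 change was 0.692 (quartiles 0.534 and 0.883), and 875 genes (81.6%) had a ratio under 1.

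The infection index, from 1025 genes that rose and 47 that fell, stood at 0.252 ± 0.2 (SD, n = 5) in Col-3 mock and -0.212 ± 0.17 in nup62 mock libraries, a difference of -0.464 (exact permutation p = 0.0159, adjusted p = 0.0159). In infected libraries it stood at 3.47 ± 0.244 in Col-3 and 2.52 ± 0.083 in nup62, a difference of -0.946 with no overlap (exact permutation p = 0.00794, the smallest the test can give, adjusted p = 0.0159). The index is a level, so the infected difference includes the one already present in mock libraries and is not a difference in response. The mock difference depended on the choice of genes, with 0.171 (adjusted p = 0.0238) over all genes past the threshold. It was -0.300 (adjusted p = 0.114) without Col3_mock replicate 1 and nup62_mock replicate 5, and -0.391 (exact adjusted p = 0.0556) without the latter alone. Leaving out any other single library kept the call.

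**Figure D4:**
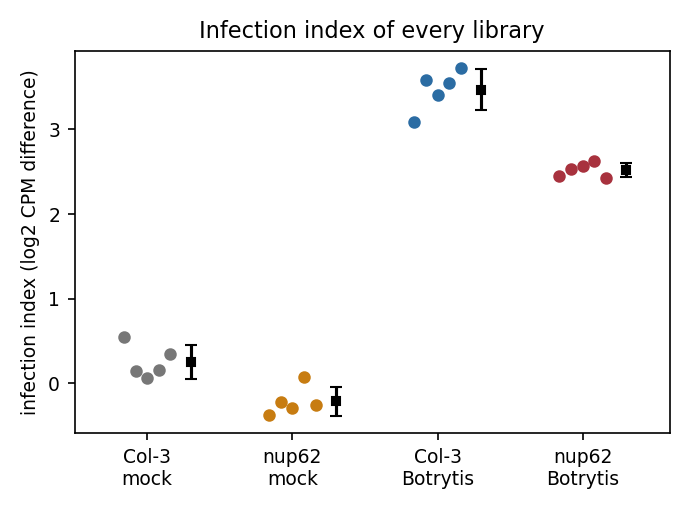
Infection index of each library (points; difference of mean log2 CPM between genes that rise and genes that fall on infection), with group means and SD (squares and bars, n = 5). Infected libraries lie at 3.08 to 3.72 in Col-3 and 2.43 to 2.62 in nup62.

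**Figure D5:**
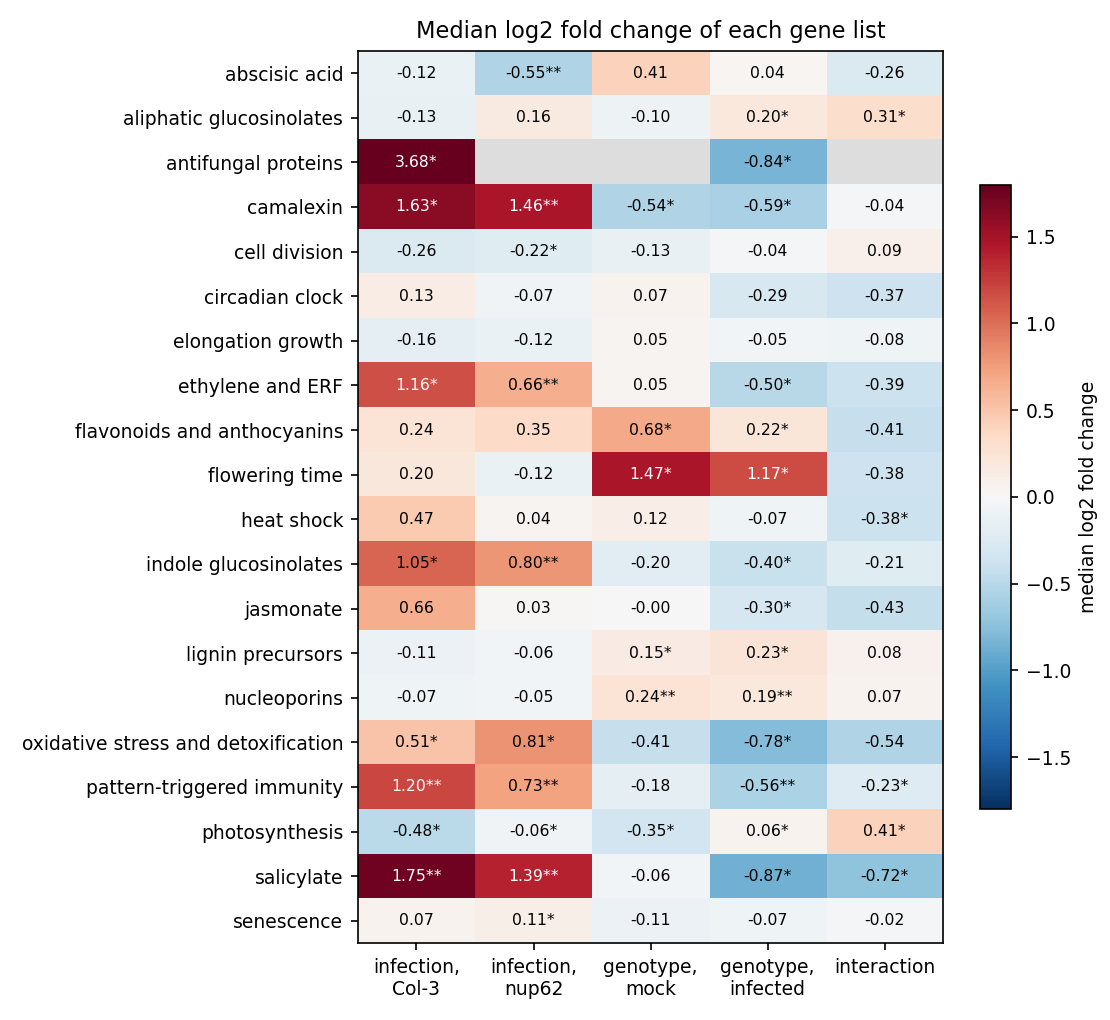
Median log2 fold change of each tested list (rows of the map) in the 5 comparisons (columns); 1 star marks a camera adjusted p under 0.05, and 2 stars mark that the call also held with an estimated correlation. The antifungal list is grey in the 3 comparisons that use nup62 mock libraries, where some of its genes are at 0, and reads 3.68 and -0.84 in the other 2. Salicylate reads 1.75, 1.39, -0.06, -0.87 and -0.72 from left to right.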

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

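The tests chosen only after the result was seen were the library scaling tests of the photosynthesis genes and of the nucleoporin genes in mock libraries and the test of equally lowered responses, whose bound was also set with the values known; removing the length and GC trend was itself chosen after seeing the data. Each value was marked for 1 of 2 reasons: a library far from the other 4 of its group, or an infection effect that differed between the genotypes in a test of the difference itself.

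In 412 groups of 5 libraries, covering 101 genes, library totals and the infection index, 13 values from 10 libraries stood apart by the ratio of their gap to the range of the group; 20.6 are expected by chance, about 1 in 20. Col3_Botrytis replicate 1 was low in ICS1 (0.774), CERK1 (0.738) and VSP1 (0.727), and Col3_Botrytis replicate 4 high in PORA (0.882). Among nup62_Botrytis libraries, replicate 4 was high in CYP71A13 (0.837), replicate 3 high in DREB2A (0.901) and replicate 1 low in AP1 (0.721). Among nup62_mock libraries, replicate 3 was low in RBCS2B (0.712) and PSAO (0.805), replicate 4 low in AT1G56000 (0.772) and replicate 5 high in HCT (0.818). Among Col3_mock libraries, replicate 1 was high in WRKY38 (0.712) and replicate 2 low in ERF1B (0.739).

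The infection effect differed between the genotypes for 43 of 69 genes named in infection or interaction (edgeR interaction, adjusted p under 0.05), 25 of them lower in nup62; many of the 69 were named for their interaction, so this share tests nothing, and over all 19735 tested genes it was 38.01%. The lower log2 differences were WRKY38 -2.818, WRKY62 -2.708, NUDT21 -2.288, PUMP4 -2.246, CAF1-9 -2.237, AT1G56120 -2.002, LHT7 -1.956, PROPEP2 -1.744, ERF1B -1.723, PCR1 -1.580, WRKY53 -1.379, NCED3 -1.248, DREB2A -1.226, PCC1 -1.093, LURP1 -1.087, WRKY33 -1.012, LYK5 -0.942, EDS1 -0.822, ERF104 -0.806, ROF1 -0.685, SAG21 -0.627, NDA2 -0.477, PEN2 -0.349, ICS1 -0.289 and CERK1 -0.173. The higher ones were GAD4 1.165, SAUR62 1.061, AT1G15125 1.009, AT1G49470 0.964, AT1G56000 0.955, NUP62 0.943, FBA5 0.829, GSTU17 0.740, SOT18 0.729, LHCB4.2 0.724, RCA 0.583, AT1G62510 0.572, RBCS1B 0.521, AMT1-2 0.505, RBCS2B 0.5, RD22 0.499, ORA59 0.494 and LHCB1.1 0.485. WRKY62 was already higher in nup62 than in Col-3 in mock libraries, by 2.67 ± 0.43 (log2, SE, edgeR adjusted p = 1.01e-05), at low counts in Col-3 mock. The call of PROPEP2 was lost in 10 fits without 1 library (-1.478, adjusted p = 0.094, without nup62_mock replicate 4) and with a replicate block (-1.669, adjusted p = 0.062). The median differences of lists called by camera were salicylate -0.724, heat shock -0.383, pattern-triggered immunity -0.226, aliphatic glucosinolates 0.311 and photosynthesis 0.408; none of these 5 calls held with an estimated correlation (adjusted p from 0.383 to 0.553).

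The smaller infection response of nup62 was weighed against technical causes. With the length and GC trend of each library removed, the median ratio of responses was 0.711, and the highest ratio over 3 other scalings was 0.701, against 0.692 as reported, so neither the trend nor the scaling makes the whole difference. A lighter or later infection of the nup62 seedlings stays open, since fungal reads were not analysed here. The camalexin genes that rose in Col-3, looked at after their ratios were seen, had a median ratio of 0.96 and quartiles of 0.747 and 1.072, which span the upper quartile of 0.883 over all responding genes; of 8 antifungal genes 1 lay under 1 (median 1.266, quartiles 1.215 and 1.69), 3 of the 8 having no count in nup62 mock libraries and thus no firm ratio. Median ratios of the other rising lists were 0.63 (salicylate), 0.564 (pattern-triggered immunity), 0.53 (ethylene and ERF), 0.836 (indole glucosinolates) and 0.647 (oxidative stress). List genes were taken at any size of rise in Col-3, while the responding genes changed at least 2-fold in the mean infection effect. A lower response of the mutant to the same infection may be the source and stays a hypothesis.

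Photosynthesis genes fell on infection in Col-3 and much less in nup62, but with an estimated correlation no list call held (adjusted p = 0.147 in Col-3, 0.69 in nup62 and 0.383 for the interaction). Medians that use the Col-3 mock libraries were -0.483 (infection in Col-3), -0.346 (nup62 against Col-3 mock) and 0.408 (interaction). Those without them were -0.059 (infection in nup62) and 0.062 (nup62 against Col-3 under infection). A shift of the Col-3 mock libraries alone can thus not be told apart from a differing infection response. Library scaling as the whole cause is argued against by a lowest median interaction of 0.233 over 3 other scalings, against 0.408. The trend over length and GC cannot be told apart from a difference in these genes: with it removed the median was 0.176. Random lists matched on level, exon length and GC had a median of 0.36, and 97.84% of them lay below the list. The cause of the trend was not tested, and a difference in RNA quality or in library preparation between groups would be confounded with the groups.

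Nucleoporin genes were higher in nup62. In mock libraries the lowest median difference over 3 other scalings was 0.225, against 0.242, which argues against scaling. The trend over length and GC remains open there, since removing it left 0.121; 99.82% of matched random lists lay below the list, which counts against the trend as the whole cause. In infected libraries the median was 0.193 with the trend removed and 0.193 before, which argues against the trend. A response of the cell to a damaged pore may raise these genes, a hypothesis that was not tested.

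For each count of genes, 100 splits of the same libraries into groups of the same sizes were fitted with edgeR, and 1 of 100, the real one, gave as many genes. That share is the smallest this test can give. Real counts were 11464 for infection in Col-3 (highest other 5917) and 5562 for infection in nup62 (highest other 253). For nup62 against Col-3 they were 10258 in mock (highest other 4600) and 7900 in infected libraries (highest other 1238). The interaction had 7501 (highest other 0). Mixed splits put real group differences into the spread within groups, which lowers their counts. For the interaction, genotypes were shuffled within each treatment, and 99 other splits gave 0. Genotype differences alone can bring this about, so the splits cannot decide whether an interaction exists. At an unadjusted p under 0.05, the real interaction had 9099 genes and the highest other split 3949; no other tool was run on the splits.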

How the results depend on the processing

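Leaving out Col3_mock replicate 1 and nup62_mock replicate 5, and removing the length and GC trend, were chosen after seeing the data. Counts of changed genes stayed within 1.5 times the reported ones under every alternative run and without each single library. For the interaction they ran from 6228 to 8137 over the alternatives and from 6835 to 7742 without single libraries, and for infection in nup62 from 5281 to 6424 and from 5043 to 5646. Genes changed at least 2-fold fell with limma-trend on log2(FPKM + 1) to 996, 362, 117, 175 and 220 (infection in Col-3, in nup62, genotype in mock, under infection, interaction), where adding 1 shrinks changes of genes with low FPKM (ALD1 in nup62 from 3.252 to 0.652), and with a stricter filter, which tests fewer genes, to 467 and 398 for genotype in mock and under infection. The limma-trend alternative, which changes test, scaling and offset at once, also moved the median of all genes by 0.1184 in infection in Col-3 and by -0.1209 in the interaction; the cause was not tested. Of 11464, 5562, 10258, 7900 and 7501 calls, 80.9%, 89.9%, 79.9%, 90.8% and 66.5% were kept with the trend removed. Of 158 called results of named genes 149 held under every alternative and without each single library. Many of these genes were named for large or clear changes in the same data, so that share does not stand for all calls. PDF1.2A in the interaction reversed with limma-trend on log2(FPKM + 1) (-1.556), where its fitted value rests on a group at 0, and LHCB1.1 in mock reversed with the trend removed (0.164, adjusted p = 0.000528). Of 45 list calls 12 held under the same alternatives and 33 were lost, each at least with an estimated correlation. In exact permutation tests, the index difference in mock reversed over all genes past the threshold (0.171) and missed 0.05 as a median over genes (-0.336, exact adjusted p = 0.151), with both libraries left out (-0.300, adjusted p = 0.114) and with a replicate block (-0.464, exact sign-flip p = 0.0625, the smallest that test can give). Without single libraries it ran from -0.599 to -0.346, with exact adjusted p = 0.0556 at -0.391 without nup62_mock replicate 5. The infected difference kept its sign throughout; with the replicate block it was -0.946 (exact sign-flip p = 0.0625), and without single libraries it ran from -1.036 to -0.689. The causes of these changes were not tested. Replicate numbers do not pair libraries: over 30 pairs with the same number the mean correlation was -0.0125. The correlation of infection effects was 0.299 (Spearman 0.3033) with no filter, which adds genes near 0, 0.7477 with the stricter filter and 0.8108 (Spearman 0.7454) over genes past the threshold in the mean infection effect; without single libraries it ran from 0.6352 to 0.6641 (Spearman 0.3903 to 0.4839). Depth limits genes at a few counts, such as the PDF1.2 copies and AP1, to bounds or wide errors.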

Other observations

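The tests of transcription factor families, of genes shared between treatments, of transport genes and of the neighbourhood of NUP62 were thought of after the results of single genes were seen. Families of transcription factors with at least 20 tested members were tested with camera, 18 in each comparison. WRKY factors, many of which serve immunity, rose on infection: 45 of 59 in Col-3 (1 fell; adjusted p = 2.08e-15, and 0.00949 with an estimated correlation) and 32 in nup62 (0 fell; adjusted p = 3.98e-12, and 0.0396). WRKY54 rose by 4.05 ± 0.22 (log2, SE) in Col-3 and 2.64 ± 0.21 in nup62, and WRKY70 by 3.54 ± 0.11 in Col-3. Under infection 32 were lower and 3 higher in nup62 (adjusted p = 4.89e-06, and adjusted p = 0.224 with an estimated correlation), and the response was lower for 28 and higher for 0 (adjusted p = 9.13e-07, and adjusted p = 0.0915); WRKY40 stood at -1.54 ± 0.21. In mock libraries 34 of 79 MYB factors were higher and 6 lower in nup62 (adjusted p = 0.0144, and adjusted p = 0.0954 with an estimated correlation), while the infection response was lower for 22 and higher for 0 (adjusted p = 0.0229, and adjusted p = 0.0915). Of 26 MADS factors of the MIKC type 13 were higher and 2 lower (adjusted p = 0.0218, and adjusted p = 0.198), among them SEP3 (AT1G24260, 2.21 ± 0.17) and MAF5 (1.83 ± 0.22). Of 31 GRAS factors 13 were lower and 4 higher (adjusted p = 0.0144, and adjusted p = 0.0954). Of 75 NAC factors 31 rose and 3 fell on infection in Col-3 (adjusted p = 0.0188, and adjusted p = 0.156 with an estimated correlation), and 24 were lower and 2 higher in nup62 under infection (adjusted p = 0.0451, and adjusted p = 0.224). On infection in nup62, 8 of 38 HD-ZIP factors fell and 0 rose (adjusted p = 0.0391, and adjusted p = 0.253), and 14 of 58 MYB-related factors fell and 2 rose (adjusted p = 0.03, and adjusted p = 0.253). With the length and GC trend removed, the HD-ZIP call (camera adjusted p = 0.0755) and the NAC call under infection (0.051) were lost. The same removal added a call of C3H factors in mock libraries (camera adjusted p = 0.031). In the interaction it added C2H2 (0.0176), C3H (0.0131), ERF (0.0131) and Trihelix (0.0349) factors.

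The mutant differed from Col-3 in a shared set of genes with and without the fungus. In comparisons that share no library, 230 genes differed at least 2-fold in the same direction, 134 higher and 96 lower in nup62, against 6 and 5.7 expected of independent lists. Across genes the 2 sets of differences had a Pearson correlation of 0.463.

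Genes of nuclear transport outside the pore stood among the strongest differences: XPO1B was higher in nup62 by 1.97 ± 0.06 (log2, SE) in mock and 1.38 ± 0.06 in infected libraries, RAN1 by 1.62 ± 0.04 and 1.92 ± 0.05, RAN2, a near copy of RAN1, by 1.04 ± 0.05 and 1.28 ± 0.05, and NTF2B by 1.14 ± 0.05 and 1.26 ± 0.05. The hypothesis that transport receptors and Ran factors are raised together was tested on 30 other such genes, 26 of which passed the filter. In mock libraries 16 were higher and 2 lower (16 and 2 adjusted over the list alone; camera p = 0.000102, and 0.0363 with an estimated correlation), and in infected ones 16 and 0 (17 and 0 over the list alone; p = 1.43e-10, and 0.00191). With the length and GC trend removed, the mock median fell from 0.193 to 0.092, the higher genes from 16 to 12, and the p was 0.00867. Exportin XPO1A stood at 0.62 ± 0.04 and 0.35 ± 0.04, and RANGAP1 at 0.32 ± 0.05 and 0.56 ± 0.05. A joint rise of nuclear transport genes in this mutant may be a response to the pore defect; these data hold 1 mutant line only.

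Genes linked to NUP62 and carried over from another parent would differ near the gene. Within 2 Mb of NUP62, 7 of 724 tested genes (0.967%) were among the 230 that differed in both treatments, against 223 of 19010 elsewhere (1.173%; Fisher exact p = 0.859), which argues against such a stretch as the source of most shared differences.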
